A study of Mus musculus with 9 samples.

How the data were processed

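RNA from male SJL/J and C57BL/6J mice aged 8 weeks was compared on 9 spotted arrays, 3 for brain, 3 for kidney and 3 for liver. On each array a pool of RNA from 5 SJL/J mice, labelled with a far-red Alexa Fluor dye, was hybridised against a pool from 5 C57BL/6J mice, labelled with an orange Alexa Fluor dye, with 20 ug of pooled RNA in each labelling reaction. Per the series design text, the 3 arrays of a tissue were technical replicates of the same 2 pools and the dyes were not exchanged. The p-values given here therefore measure only the spread between arrays of the same pools, not the spread between mice. A dye or probe effect particular to a gene is added to the strain ratio within each tissue, and it cancels in a difference between tissues only as far as the same probe behaves alike in both. The channel 1 tissue label of the kidney and liver arrays reads brain, whereas their titles, source names and channel 2 labels read kidney and liver, and the titles were followed.

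The deposited table held 1 log ratio per spot and array, 23040 spots on 9 arrays with 0 missing values, and no other column. Per the submitters' processing notes, R 2.0.0 and limma were used by the authors. The base of the deposited log ratios was taken as log2, which is limma's convention, and the labels do not state it. The direction was likely SJL/J over C57BL/6J, from the order of the strains in the titles, the dyes and limma's convention of red over green. Nnt, the nicotinamide nucleotide transhydrogenase gene that is partly deleted in C57BL/6J, lay above 0 on 9 of 9 arrays, from 0.15 to 1.06. It passed the test in brain (0.61, adjusted p = 0.0444) and kidney (0.67, adjusted p = 0.0237) but not in liver (0.48, adjusted p = 0.0887). These arrays share pools within a tissue and 1 dye orientation, so they are not 9 independent checks of the direction. The sorted values of the 9 columns were identical, so the authors had made the distributions of the arrays equal before deposit, with a median of 0.01 and a range of -3.91 to 5.09 on each array. Background correction and any scaling within arrays are not given in the sources used here. Spot intensities were not used here, so no filter on dim spots could be made and only the number of arrays limits the stated precision.

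Probes were named through the platform annotation. Of the probes, 16874 carried a single gene symbol (15096 genes), 134 carried several and 6032 were unnamed here. Gene identifiers of 16196 probes matched the reference gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used only for names and for which genes neighbour each other. Gapdh was spotted 232 times.

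A linear model with 1 coefficient per tissue was fitted to the 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 6 residual degrees of freedom and gave a prior of 4.24 degrees of freedom with a prior SD of 0.20. Each tissue's mean log ratio was tested against 0, the differences between tissues by contrasts, and tissue dependence by the moderated F-test, all two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A shared ratio was tested on 3 values per probe, each the mean of the arrays of a tissue. Values are means with the SD over 3 arrays. In gene lists, probes of a gene were averaged and camera was used with a preset correlation of 0.01, adjusted over 129 tests (43 lists with at least 5 measured genes in each of 3 tissues, of 44 lists written). Members were counted over all genes tested and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry, which asks only whether the genes of a list move one way, was run as well.

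Before the data were examined, the genes to be named were set as the 10 highest and the 10 lowest per tissue among probes with a single symbol that passed the test with the same sign on all 3 arrays, a gene counting once by its most extreme probe. To these were added the 10 highest and the 10 lowest means among probes that passed in all tissues with the same sign, the 10 largest differences among genes with opposite calls in 2 tissues, up to 4 members of each list, and Nnt. After the data showed low ratios at probe numbers that are multiples of 8, the rule was repeated without those 2880 probes (12.5% of the table), and counts were also given for the 14692 probes with a single symbol and another number.

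Data were simulated with 1 spread per probe, estimated over all tissues, and 200 changed probes per tissue. Changes of 2 log2 units were recovered for 98.5% of changed probes in brain, 95.5% in kidney and 95.5% in liver, and changes of 0.5 for 28.4%, 35.8% and 25.4%. All simulated arrays varied alike, whereas the real brain arrays had residual SDs of 0.25, 0.23 and 0.32 against 0.20 to 0.21 on the others. The brain figures therefore do not cover the larger spread of the real brain arrays. False calls made up 8.55% of the calls in brain, 3.97% in kidney and 1.42% in liver. For tissue dependence, changes of 2 were recovered for 95.5% of changed probes, with 3.74% of calls false. In a simulated table with 1 list shifted in liver, 1 of 129 list tests was called. The simulated genes varied independently of each other, so this says nothing about false list calls where genes of a list are correlated.

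Alternatives fixed beforehand were centring, equal spread of arrays, filters on missing values, robust eBayes, each array left out in turn, a fit on a tissue's own arrays, 1 value per gene, a test against a fold of 1.2, a 2-fold limit, a replicate block and tissue as a random block. Added after the data were seen were the sets of probes above, a term for an array set, fits and list tests within that set, and a median polish of each array in blocks of 480 spots (20 lines of 24 consecutive probe numbers, taken as the print layout from the values). Figures were drawn with matplotlib 3.10.9.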

Results

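The strain ratio of gene expression, SJL/J over C57BL/6J, was measured in brain, kidney and liver, with 3 arrays per tissue. SJL/J and C57BL/6J are inbred strains of laboratory mice. Each array compared a pool of 5 males of one strain with a pool of 5 males of the other, so each value below describes 2 pools and its error (SD, n = 3 arrays) is technical. A positive log2 ratio means a higher level in the SJL/J pool, with the direction and the log base inferred as described under the processing.

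In liver, genes of the acute phase response, which liver cells secrete or express in inflammation, were higher in the SJL/J pool. Of 25 measured members, 21 rose, 0 fell and 4 did not pass the test (21 rose and 1 fell when adjusted over the list alone), with a median log2 ratio of 0.85. The list was called by camera (adjusted p = 2.73e-15, and adjusted p = 0.115 with an estimated correlation). Lcn2, a protein that binds bacterial iron carriers, rose by 3.40 ± 0.52 (SD, n = 3), Orm2, an orosomucoid of plasma, by 2.92 ± 0.27, and Apcs, the serum amyloid P component, by 2.45 ± 0.11. Mt1, a metallothionein that binds zinc, had a ratio of 4.22 ± 0.51, but the other spots of its line of 24 consecutive probe numbers had a median of 2.40, and its ratio was 1.87 (adjusted p = 0.000259, limma) after medians of lines and columns were removed. The members' median was 0.05 in brain and 0.12 in kidney. Of 23 markers of microglia and macrophages 4 rose in liver, 0 fell and 19 did not pass (4 and 0 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0543, limma's camera, and adjusted p = 0.342 with an estimated correlation). With medians of lines and columns removed this list was called as higher (adjusted p = 0.0229).

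Markers of hepatocytes, the main cell type of liver, were also higher: of 23 genes, 13 rose, 2 fell and 8 did not pass (14 and 2 adjusted over the list alone), with a median of 0.54 (adjusted p = 3.30e-05, and adjusted p = 0.113 with an estimated correlation). Mup3, a major urinary protein, rose by 1.42 ± 0.26 (SD, n = 3), Serpina1a, a protease inhibitor of plasma, by 1.14 ± 0.31, and Alb, serum albumin, by 1.06 ± 0.30, while Tdo2, which opens tryptophan breakdown, had a ratio of -1.69 ± 0.33. Of these markers, 4 also belong to the acute phase list.

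Genes of fatty acid oxidation and other targets of PPAR alpha, the nuclear receptor of the fasting liver, were lower in the SJL/J pool. Of 30 genes, 22 fell, 0 rose and 8 did not pass (22 fell adjusted over the list alone), with a median of -0.91 (adjusted p = 1.24e-11, and adjusted p = 0.173 with an estimated correlation). Cyp4a10 and Cyp4a14, omega-hydroxylases of fatty acids, had ratios of -3.28 ± 0.78 and -3.08 ± 0.39 (SD, n = 3). Acaa1a, a thiolase of peroxisomes, had -1.89 ± 0.20, and Hadhb, a subunit of the mitochondrial trifunctional protein, -1.76 ± 0.30. The same list had a median of 0.03 in brain and 0.14 in kidney.

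Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, were lower in the SJL/J liver pool too. Of 69 genes, 32 fell, 1 rose and 36 did not pass (42 fell and 3 rose adjusted over the list alone), with a median of -0.48 (adjusted p = 6.37e-06, and adjusted p = 0.873 with an estimated correlation). Uqcrfs1, the Rieske protein of complex III, had a ratio of -1.35 ± 0.52 (SD, n = 3), Atp5j, a subunit of ATP synthase, -1.26 ± 0.57, and Cox4i1, of cytochrome oxidase, -1.18 ± 0.60. Among 60 ribosomal protein genes 13 fell, 0 rose and 47 did not pass (10 fell adjusted over the list alone), led by Rpl27 at -1.22 ± 0.49 and Rps20 at -1.19 ± 0.59, with a median of -0.28 (adjusted p = 0.00220, and adjusted p = 0.983 with an estimated correlation). With medians of lines and columns of spots removed, the ribosomal call was lost (median -0.18, adjusted p = 0.0698).

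Lists of liver metabolism of drugs and bile acids were lower as well. Of 50 cytochrome P450 genes 23 fell, 3 rose and 24 did not pass (24 fell and 6 rose adjusted over the list alone), with a median of -0.34 (adjusted p = 5.35e-05, and adjusted p = 0.113 with an estimated correlation). Besides the Cyp4a genes, Cyp3a13 had a ratio of -1.85 ± 0.84 (SD, n = 3) and Cyp3a16 -1.81 ± 0.24. Of 23 genes of bile acids and sterol transport 14 fell, 1 rose and 8 did not pass (16 and 1 adjusted over the list alone), with a median of -0.56 (adjusted p = 3.30e-05, and adjusted p = 0.115 with an estimated correlation). Hsd3b7, an enzyme of bile acid synthesis, had -2.23 ± 0.17, Abcb4, a phospholipid exporter of the canaliculus, -0.91 ± 0.74, and the efflux pump gene Abcc3 -1.85 ± 0.13 at a probe number that is a multiple of 8. With medians of lines and columns removed, the P450 median was -0.21 (adjusted p = 0.00602) and that of bile acids and sterol transport -0.27 (adjusted p = 0.00692). Of 21 glutathione S-transferase genes 9 fell, 2 rose and 10 did not pass (12 and 2 adjusted over the list alone), led by Gstm2 at -2.04 ± 0.28 and Gsta1 at -1.98 ± 0.22, with a median of -0.36 (adjusted p = 0.00326, and adjusted p = 0.593 with an estimated correlation).

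Conjugating enzymes and amino acid metabolism gave calls in liver that ended when medians of lines and columns were removed. Of 15 UDP-glucuronosyl and sulfotransferase genes 8 fell, 2 rose and 5 did not pass (9 and 2 adjusted over the list alone), with Ugt2b1 at -1.80 ± 0.10 and Sult1c2 at 2.06 ± 1.17 (SD, n = 3) and a median of -0.49 (adjusted p = 0.0222, adjusted p = 0.274 with an estimated correlation, and 0.276 with the medians removed, when the median was -0.20). Of 39 genes of amino acid and urea metabolism 15 fell, 4 rose and 20 did not pass (19 and 4 adjusted over the list alone), with Glud1, glutamate dehydrogenase, at -1.59 ± 0.08, Otc, of the urea cycle, at -0.86 ± 0.68, and a median of -0.32 (adjusted p = 0.0222, adjusted p = 0.222 with an estimated correlation, and 0.591 with the medians removed, when the median was -0.11). In all, 10 of 43 lists were called in liver, 2 higher and 8 lower, and 0 of 43 with an estimated correlation, whereas fry called 19.

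**Figure D1:**
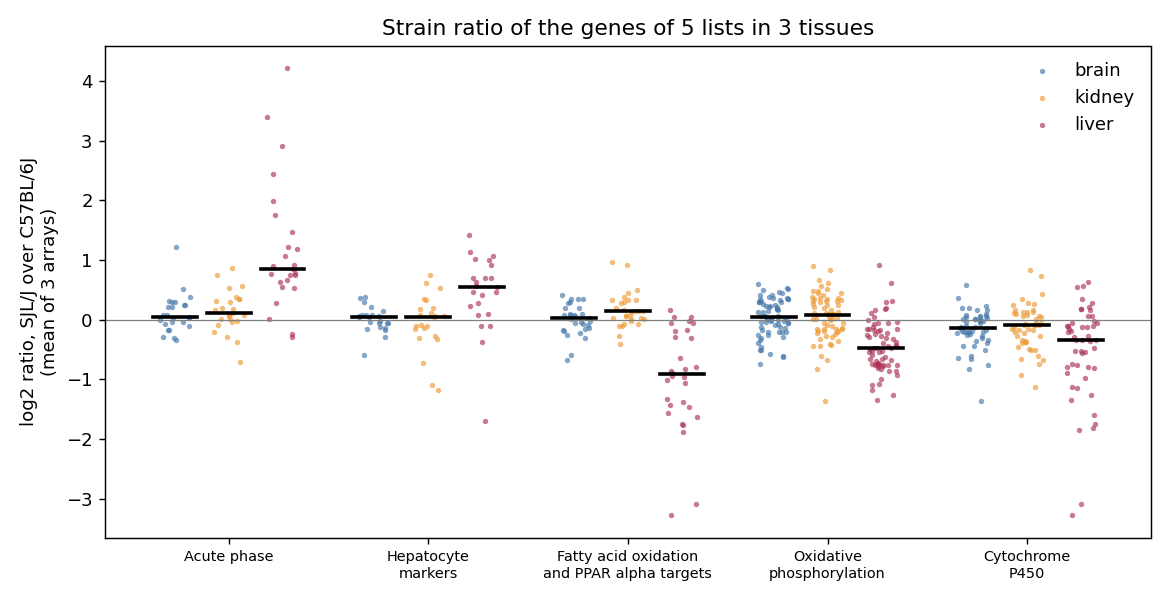
Strain ratios (log2, SJL/J over C57BL/6J, vertical axis, mean of 3 arrays) of the genes of 5 lists, with 1 point per gene, colour for the tissue and a black bar at the median. The acute phase members had a median of 0.85 in liver against 0.05 in brain and 0.12 in kidney, and the fatty acid oxidation members -0.91 against 0.03 and 0.14.

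Among single genes in liver, Dio1, which activates thyroid hormone, had a ratio of -3.11 ± 0.75 (SD, n = 3, adjusted p = 7.16e-06), and G6pc, the last enzyme of glucose release, -2.73 ± 0.13 (adjusted p = 1.64e-06). Selenbp1 and Selenbp2, which bind selenium, had -2.97 ± 0.25 and -2.62 ± 0.65, Hsd3b1, a steroid dehydrogenase, -2.63 ± 0.12, and Krtcap3 -2.92 ± 0.16. The uncharacterised 1700110I01Rik and 2310043L19Rik had -3.50 ± 0.23 and -3.06 ± 0.10. Scel, a precursor of the cornified envelope of skin, had a ratio of 4.62 ± 0.44, Gp2, a glycoprotein of pancreatic zymogen granules, 3.79 ± 0.25, Satl1 3.07 ± 0.30 and 1600010M07Rik 3.32 ± 0.65. Scel had 3.66 and 3.58 on brain replicates 1 and 2, against -1.59 on brain replicate 3 and -2.21, -0.25 and -1.69 in kidney, and 1600010M07Rik was alike (3.09 and 2.19, against -1.39, then -2.23, -0.07 and -1.51).

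Tuba4a, an alpha tubulin, had 3.68 ± 0.46 (SD, n = 3) in liver at one probe and -0.79 at another. The first probe of Tuba4a had 3.03 and 2.75 on brain replicates 1 and 2, against -1.59 on replicate 3 and -2.10, -0.05 and -1.68 in kidney. Serpina1f (3.59 ± 0.17), 1700066C05Rik (3.60 ± 0.16), Manbal (3.55 ± 0.09, at a multiple of 8) and Cd209e, a lectin of immune cells (3.50 ± 0.16), lay in lines of 24 spots with medians of 2.41 or 2.40, and had 1.05, 1.04, 1.13 and 1.01 with the medians of lines and columns removed. The probe of 2310030A07Rik, at a multiple of 8, had -2.68 ± 0.39. In total 5805 probes passed in liver, 2955 higher and 2850 lower, of which 770 and 445 by at least 2-fold. Among the 14692 probes with a single symbol and a number that is not a multiple of 8, 1551 were higher and 1671 lower (220 and 230 by at least 2-fold). With 1 liver array left out, between 3273 and 3704 of all probes passed.

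In brain, the strain ratios of named genes were led by genes of varied function. Satl1, of the spermidine/spermine N1-acetyltransferase-like family, had a ratio of 3.26 ± 0.41 (SD, n = 3, adjusted p = 6.04e-06), Olfr76, an olfactory receptor, 3.01 ± 0.32, Cap1, which binds actin, 2.95 ± 0.51, and Il6ra, a receptor subunit for interleukin 6, 2.52 ± 0.60. Thbs2, a matrix glycoprotein, had 2.31 ± 0.58, Il9r, the interleukin 9 receptor, 2.25 ± 0.36, and Rfc3, of the clamp loader of DNA replication, 2.21 ± 0.80. Chst11, a chondroitin sulfotransferase, had 2.62 ± 0.15, Hba-x, an embryonic globin, 2.07 ± 0.35, and Pard3b, a polarity protein, 2.07 ± 0.70, but their other probes gave 0.04, 0.16 (at a multiple of 8) and -0.12, none of which passed.

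The lowest brain ratios away from multiples of 8 were those of 4933416M06Rik (-2.94 ± 0.68, SD, n = 3) and 4930573C08Rik (-1.77 ± 0.16), Smok2a, a sperm motility kinase gene (-1.93 ± 0.78), Erlin1, of the endoplasmic reticulum (-1.84 ± 0.84), and Atp4b, a subunit of the gastric proton pump (-1.78 ± 0.65). Stk25, a kinase, had -1.68 ± 0.16 and at a second probe -1.22 (adjusted p = 0.000431). Pilra, an inhibitory immune receptor, had -1.67 ± 0.46, Slc36a1os -1.65 ± 0.14, and Pttg1, the securin of mitosis, -1.62 ± 0.48. Atp8a1, a phospholipid flippase, had -1.61 ± 0.37. By the rule as first written, 9 of the 10 lowest brain genes lay at multiples of 8, among them 2310030A07Rik (-3.64 ± 0.47), Cdca4 (-3.14 ± 0.33), Tube1 (-3.09 ± 0.35), Clcn5 (-2.69 ± 0.12, with 0.15 at its other probe), Rhoh (-2.66 ± 0.33) and Hacd4 (-2.56 ± 0.28).

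Of 43 lists tested in brain 1 was called, that of 60 ribosomal protein genes, of which 6 rose, 0 fell and 54 did not pass (2 rose adjusted over the list alone), with a median of 0.17. Rpl29, at 0.83 ± 0.35 (SD, n = 3), and Rpl14, at 0.73 ± 0.35, led it (adjusted p = 0.0323, and adjusted p = 0.983 with an estimated correlation). The call was lost without the probes at multiples of 8 (adjusted p = 0.246) and without the array labelled brain replicate 3 (adjusted p = 0.675). It was kept with medians of lines and columns removed (adjusted p = 0.00168, median 0.20). In brain 4660 probes passed, 2386 higher and 2274 lower, of which 665 and 346 by at least 2-fold. This test used a spread shared with kidney and liver, whose arrays varied less than those of brain, and far fewer probes passed on the brain arrays alone (given below). Of the 2-fold calls in brain, 89.0% of the higher ones were unnamed and 69.1% of the lower ones lay at multiples of 8. Leaving out the array labelled brain replicate 1 gave 3024 and leaving out replicate 2 gave 2325. Of the 14692 probes with a single symbol away from multiples of 8, 1219 were higher and 1067 lower (70 and 66 by at least 2-fold), against 857 and 1123 with medians of lines and columns removed.

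In kidney, Ttll8, which adds glycine to tubulin, had the highest ratio, 4.53 ± 0.98 (SD, n = 3, adjusted p = 7.13e-06), with 2 of 3 arrays at the highest value of the table, 5.09. It was followed by Satl1 at 1.96 ± 0.04, Trnau1ap, of selenocysteine insertion, at 1.64 ± 0.06, Fabp9, a fatty acid binding protein, at 1.62 ± 0.04 (0.05 at its other probe, not passed), and Fam32a at 1.52 ± 0.14. Rfc3 had 1.51 ± 0.08, Fgfr4, a growth factor receptor, 1.47 ± 1.06, Hba-x 1.46 ± 0.29 (0.18 at its other probe, not passed), Capn10, a calpain, 1.45 ± 0.12, and Hao2, an oxidase of hydroxy acids in kidney peroxisomes, 1.42 ± 0.07. The rule as first written also took Ankrd39 (1.47 ± 1.29) and 1 of the 232 Gapdh spots (1.49 ± 0.83), both at multiples of 8. The Gapdh spots, 231 of them at multiples of 8, had a median of -0.06 in brain, -0.05 in kidney and -0.37 in liver.

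Lower in the SJL/J kidney pool were Wtap, of the RNA methylation complex (-2.21 ± 0.39, SD, n = 3, with -0.06 at its other probe), Smc3, of cohesin (-1.80 ± 0.12), Apoc1, an apolipoprotein (-1.57 ± 0.45), and Hydin, of cilia (-1.53 ± 1.05, but -0.88 with medians of lines and columns removed, its line having a median of -0.79). Sphk1, a sphingosine kinase, had -1.47 ± 1.15 and 0.07 at its other probe, Tdrd1, of the germ line, -1.44 ± 0.13, Sephs2, which makes selenophosphate, -1.43 ± 0.20, and Tcirg1, a subunit of the vacuolar proton pump, -1.41 ± 0.23. Tex46 had -1.59 ± 0.32 and 1700110I01Rik -1.58 ± 0.61. On brain replicates 1, 2 and 3, Wtap had -0.57, -1.21 and -1.98, and Tex46 -1.08, 0.13 and -2.38. Replicate 3 was thus the lowest brain array for both, as it was for Smc3, Hydin and Tdrd1, but not for Apoc1, Sphk1, Sephs2, Tcirg1 and 1700110I01Rik. By the rule as first written, 10 of the 10 lowest kidney genes lay at multiples of 8, among them 2310030A07Rik (-3.85 ± 0.11), Ccdc151 (-3.46 ± 0.11), Herc6 (-3.03 ± 0.26), Fmnl1 (-2.89 ± 0.18), Gzmc (-2.86 ± 0.28) and Cxcr2 (-2.82 ± 0.21). The kidney values of 2310030A07Rik lay at the lowest value of the table, -3.91, on 2 of 3 arrays, which limits both its ratio and its SD. Its values on brain replicates 1 and 2 and that of Cyp4a10 on liver replicate 2 lay there too. Scel on liver replicate 3 lay at the highest value, 5.09.

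No list was called in kidney by limma's camera (0 of 43, and 0 with an estimated correlation, while fry called 11). The lowest adjusted p was that of MHC class II, the genes of antigen presentation, where 3 of 12 rose, 0 fell and 9 did not pass (7 rose adjusted over the list alone), with a median of 0.30 (adjusted p = 0.114). In kidney 6681 probes passed, 3342 higher and 3339 lower, of which 592 and 491 by at least 2-fold. Of these 2-fold calls, 82.4% of the higher ones were unnamed and 82.3% of the lower ones lay at multiples of 8. Between 3855 and 4074 probes passed with 1 kidney array left out. Of the 14692 probes with a single symbol away from multiples of 8, 2160 were higher and 1289 lower (101 and 40 by at least 2-fold), against 1259 and 1283 with medians of lines and columns removed.

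**Figure D2:**
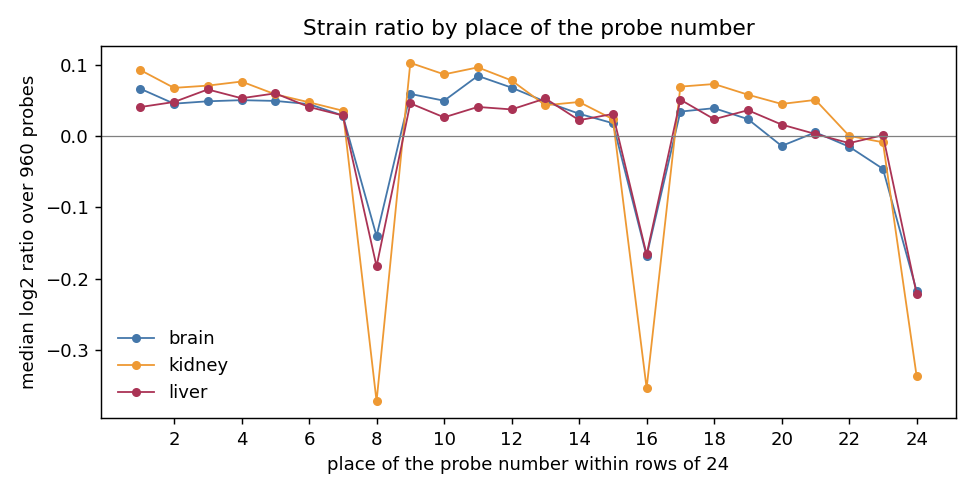
Median log2 strain ratio over 960 probes (vertical axis) by the place of the probe number within lines of 24 (horizontal axis), 1 coloured line per tissue. Places 8, 16 and 24, the multiples of 8, had medians between -0.37 and -0.14, and the probes at all other numbers a median of 0.03 in brain, 0.06 in kidney and 0.03 in liver.

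The strain ratio of several genes differed between tissues. Gp2 had -1.13 ± 0.43 in brain and 3.79 ± 0.25 in liver (SD, n = 3 each, adjusted p of the difference 2.71e-06). Acaa1a, the thiolase named above, was higher in the SJL/J kidney pool at 0.96 ± 0.10 and lower in liver at -1.89 ± 0.20 (adjusted p = 9.32e-06). Hspa8, a constitutive chaperone, had -0.76 ± 0.11 in kidney and 2.98 ± 0.70 in liver at one probe, whereas its other probe, at a multiple of 8, gave -0.57 in liver. Rny1, a small RNA bound by the Ro protein, had -0.69 ± 0.27 in kidney and 2.69 ± 0.24 in liver, and 1700086P04Rik, at a multiple of 8, -0.75 ± 0.02 and 3.11 ± 0.05. On brain replicates 1, 2 and 3, Rny1 had 1.53, 1.38 and 0.11, and Hspa8 0.60, 0.69 and -0.38. The same arrays gave -0.04, -0.04 and -0.64 for 1700086P04Rik, and 0.23, 0.26 and 0.75 for Acaa1a. In each of these genes brain replicate 3 was the brain array nearest to kidney. For the kidney values, an array set that joins brain replicate 3 to kidney therefore cannot be told apart from the tissue. Brain replicates 1 and 2 would share the other set with liver, and liver still stood apart from them in each of these genes. For Acaa1a, 0.23 and 0.26 stood against -1.89, and for Rny1, where the gap was smaller, 1.53 and 1.38 against 2.69. Serpina1f, Cd209e, Ear-ps1, Cd244a, Fam120b, Tfrc, the transferrin receptor, and Abl1, a tyrosine kinase whose probe is at a multiple of 8, were also called with opposite signs. Their liver values came from the 2 lines of spots with medians of 2.40 and 2.41, and the liver ratio of Tfrc was -0.04 and that of Ear-ps1 0.30 with the medians removed, neither of which passed. The kidney ratios of Rny1 (-0.63, adjusted p = 0.0715), 1700086P04Rik (-0.28, 0.107), Cd209e (-0.38, 0.129) and Abl1 (0.05, 0.802) did not pass either with the medians removed, nor did the brain ratios of Serpina1f (-0.59, 0.0526) and Ear-ps1 (-0.53, 0.0865).

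The acute phase list differed between brain and liver (adjusted p = 1.37e-13, camera) and between kidney and liver (adjusted p = 6.91e-11), and so did fatty acid oxidation (adjusted p = 1.42e-12 and 1.87e-13). With an estimated correlation these gave adjusted p = 0.149 and 0.171 for acute phase, and adjusted p = 0.149 and 0.149 for fatty acid oxidation. Markers of hepatocytes (adjusted p = 0.000206 and 0.000656), oxidative phosphorylation (3.71e-06 and 6.30e-05), ribosomal protein (2.24e-07 and 0.000108), bile acid and sterol transport (0.00938 and 0.00938), glutathione S-transferase (0.0160 and 0.00938) and cytochrome P450 genes (0.0294 and 0.0419) also differed from liver in brain and kidney. UDP-glucuronosyl and sulfotransferase (0.0437) and microglia and macrophage markers (0.0152) did so for brain. With an estimated correlation none of these lists was called by camera (lowest adjusted p = 0.149). On brain replicates 1 and 2 and the liver arrays alone, acute phase (adjusted p = 2.20e-13, and adjusted p = 0.345 with an estimated correlation) and fatty acid oxidation (2.47e-09, and 0.226) still differed with the preset correlation.

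The moderated F-test called 4604 probes as dependent on the tissue. Between brain and kidney 1215 probes differed (598 with the higher ratio in brain), between brain and liver 2132 (957 in brain) and between kidney and liver 4253 (2092 in kidney). Among the 14692 probes with a single symbol away from multiples of 8 these were 666 (229 higher and 437 lower in brain), 1416 (753 and 663 in brain) and 2463 (1595 and 868 in kidney). Calls of opposite sign were made for 97 probes in brain and kidney, 129 in brain and liver and 351 in kidney and liver. Of these, 58, 89 and 186 had a single symbol away from multiples of 8. The count between brain and kidney rose to 3229 without the array labelled brain replicate 3, which stood nearer to the kidney arrays than to the other brain arrays, against 2378 then between brain and liver. It was 183 without replicate 2, 643 without replicate 1, 289 to 348 without a kidney array and 693 to 808 without a liver array. Between brain and liver it was 1253 without brain replicate 2 and 1101 to 1376 without a liver array. Between kidney and liver it was 2227 to 2772 without a kidney or liver array. The F-test then called 2531 to 2920. With a term for the array set that joins brain replicate 3 to kidney, kidney against liver fell from 4253 to 617, brain against kidney to 352 and the F-test to 2442, while brain against liver gave 2378. This term rests only on brain replicate 3 against replicates 1 and 2. Differences from kidney are then less precise, which by itself lowers their counts. The term takes up brain replicate 3 in full, so the brain against liver count is that without this array.

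**Figure D3:**
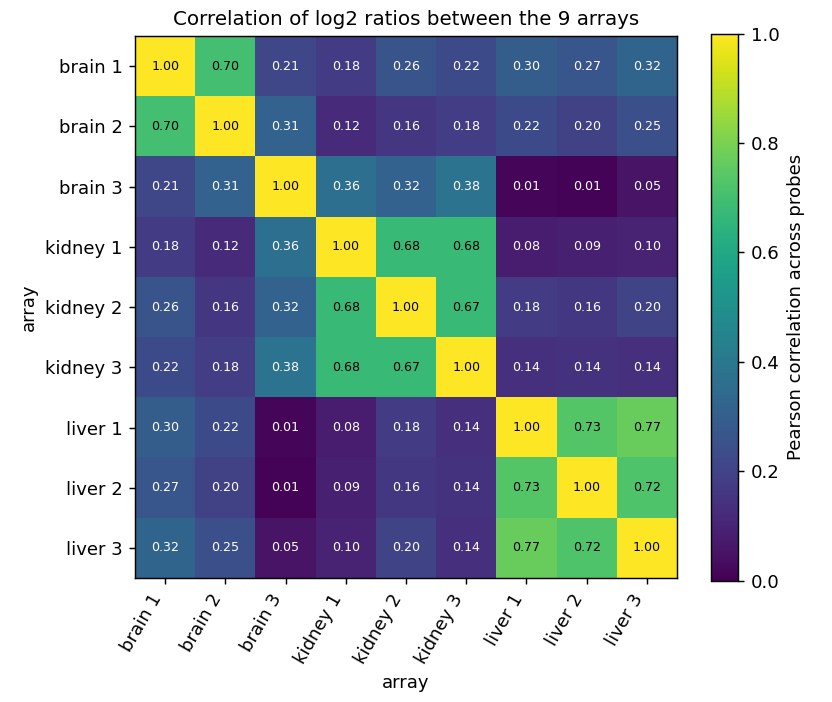
Pearson correlation of the log2 ratios between the 9 arrays across the 14692 probes with a single symbol away from multiples of 8, with the arrays on both axes and the value in each cell. The array labelled brain replicate 3 had 0.21 and 0.31 with the other brain arrays and 0.32 to 0.38 with the kidney arrays, whereas brain replicates 1 and 2 had 0.70 with each other.

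Several genes had a strain ratio of the same sign in brain, kidney and liver. Satl1 had a mean of 2.76 ± 0.70 (SD over 3 tissues), Lig3, a DNA ligase, 1.69 ± 0.60, Rfc3 1.58 ± 0.60, and Irs2, which relays the insulin signal, 1.30 ± 1.07, with 2.54 in liver. Celsr1, a cadherin of planar polarity, had 0.68 in brain, 1.18 in kidney and 2.64 in liver. Hba-x had 1.48 ± 0.59, while its other probe, at a multiple of 8, had 0.16, 0.18 and 0.17 and passed in none of the 3. Il9r had 1.40 ± 0.73, 6330407A03Rik 1.19 ± 0.34, Meis1, a homeobox factor, 1.08 ± 0.29, and Mgp, which inhibits calcification, 1.04 ± 0.25. Lower in all 3 tissues, away from multiples of 8, were Hydin (-1.75 ± 0.60), Pttg1 (-1.41 ± 0.80), Psrc1, of the mitotic spindle (-1.04 ± 0.14), Sephs2 (-1.03 ± 0.42), Amdhd1, of histidine breakdown (-1.02 ± 0.52), and Nudt19, a coenzyme A hydrolase (-1.02 ± 0.35). With them were 1700021K10Rik (-0.95 ± 0.21), Rbm12b2 (-0.92 ± 0.46), Gas2l3, which links actin and microtubules (-0.92 ± 0.17), and Adcy10, the soluble adenylyl cyclase (-0.90 ± 0.24). With medians of lines and columns removed, Rfc3, Irs2, 6330407A03Rik, Pttg1, Psrc1 and Nudt19 no longer passed in all 3 tissues. In limma's test of a shared ratio over the 3 tissue means, Irs2 (adjusted p = 0.161), Celsr1 (0.105) and Il9r (0.0557) did not pass. Nor did Pttg1 (0.0684), Rbm12b2 (0.0657) and Amdhd1 (0.0623). By the rule as first written, 10 of the 10 lowest lay at multiples of 8, from 2310030A07Rik (-3.39 ± 0.62), Ccdc151 (-2.87 ± 0.52) and Cdca4 (-2.84 ± 0.62) to Fam111a (-2.33 ± 0.30).

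Of all probes, 548 were called higher in all 3 tissues, against 44.4 from independent lists, and 571 lower, against 40.8. The 1119 together became 664 without liver replicate 3. Among probes with a single symbol away from multiples of 8 these were 109, against 18.9, and 111, against 10.7. Most of the 548 were unnamed (438), and most of the 571 lay at multiples of 8 (402). Of 317 probes with a mean over 1 in each tissue, 314 were unnamed and 175 lay in 25 runs of at least 4 adjacent numbers. The figures for independent lists leave out any dye, probe or place effect common to the tissues. The test of a shared ratio over the 3 tissue means passed 874 probes, 542 higher and 332 lower, of which 594 were unnamed and 71 had a single symbol away from multiples of 8. Refitted on all 14692 such named probes alone, limma passed 0. In the fit on all probes, 1815 of the 14692 had an unadjusted p under 0.05. The mean ratios of brain and kidney had a Pearson correlation of 0.66 (Spearman 0.46) across all probes, brain and liver 0.54 (0.40), and kidney and liver 0.43 (0.30). Across the named probes away from multiples of 8 the Pearson values were 0.35, 0.25 and 0.17. Probes are not independent replicates, and any dye or probe effect common to the tissues is contained in each of these values.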

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

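Of the tests in this part, the tests of differences between tissues were planned and that of the place of the spots for the liver pattern was set before its result was seen; the others, the counts over other splits included, were chosen afterwards.

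In liver, acute phase genes were higher in the SJL/J pool and fatty acid oxidation genes lower, and both lists differed between tissues (acute phase brain against liver, adjusted p = 1.37e-13, and kidney against liver, adjusted p = 6.91e-11; fatty acid oxidation 1.42e-12 and 1.87e-13; with an estimated correlation 0.149, 0.171, 0.149 and 0.149). The place of the spots was argued against as the whole cause, since the acute phase median stayed at 0.80 with medians of lines and columns removed. A lower share of hepatocytes was argued against by 19 hepatocyte markers outside the acute phase list (median 0.46, SD 0.68). Of these, 13 lay above and 3 below both other tissues. Lists of P450, bile acid and glutathione S-transferase genes were lower in liver, however, so this holds for the listed markers only. A dye or probe effect common to the tissues was argued against for fatty acid oxidation, where the median difference between liver and kidney was -0.99 (SD 0.84, 29 of 30 genes lower in liver). For acute phase the difference from the mean of brain and kidney was 0.87, but without intensities it is unknown whether these genes were above background there, so this effect cannot be told apart from a strain difference. With 1 pool per strain and tissue, the state of the pooled mice at sampling, such as an infection or the feeding state, may also account for the pattern and stays open beside the strain difference that the design names.

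Of the 115 probes below -1 in all 3 tissues, 95.65% (110) lay at numbers that are multiples of 8, against 12.5% of all probes. This share restates the pattern and so does not test the place of the spots as its cause, which stays open. Gapdh, with 231 of 232 spots at these numbers, had medians of -0.06 in brain, -0.05 in kidney and -0.37 in liver. All probes at these numbers had -0.17, -0.36 and -0.19. The Gapdh medians thus lay above those of all such probes in brain and kidney and below in liver, but a strain ratio of Gapdh itself was not tested. Single Gapdh spots ranged from -1.54 to 1.47 in brain, -2.53 to 1.49 in kidney and -1.51 to 0.64 in liver. Spots of 1 gene at these numbers were therefore not alike, and single spots reached ratios as low as those of some genes named above. A strain difference of the genes was argued against, since other probes of 10 of these genes had a median of -0.0434 (SD 0.27). That test was first run over 167 probes, most of them of a single gene, and then changed to 1 value per gene.

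The array labelled brain replicate 3 stood nearer to the kidney arrays than to the other brain arrays. Kidney RNA in full in place of brain RNA was argued against by a median of 0.28 of the kidney value over 65 probes (interquartile range 0.05 to 0.66). In all, 45 probes parted brain replicate 3 and kidney from brain replicates 1 and 2 and liver by over 1 log2 unit, against 3 at most for other such groupings. An array set shared with the kidney arrays could give them. A part mixture of kidney RNA was not tested on them and stays open, but it would place brain replicate 3 between the other brain arrays and kidney. For Scel (-1.59), Tuba4a (-1.59) and 1600010M07Rik (-1.39), picked for high liver ratios, brain replicate 3 lay within the range of the kidney arrays.

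The genes below were picked for calls of opposite sign and for large differences between tissues that passed their test. The pass was part of the choice and is no further support. Gp2 had a brain minus liver difference of -4.92, Serpina1f of -4.16, Ear-ps1 of -3.61 and Tfrc of -2.95. Kidney minus liver was -4.04 for Cd209e, -3.87 for 1700086P04Rik, -3.74 for Hspa8, -3.71 for Abl1, -3.41 for Cd244a, -3.38 for Rny1, -3.19 for Fam120b and 2.85 for Acaa1a. With medians of lines and columns removed, the differences of Tfrc (-0.49, adjusted p = 0.0921) and Ear-ps1 (-0.83, adjusted p = 0.0908) no longer passed, and Serpina1f had -1.64, Cd209e -1.39, Abl1 -0.88, Cd244a -0.91 and Fam120b -0.82. The other probe of Tfrc had -0.97 in liver, and the other probes of Abl1 0.33 and -1.07. For Rny1, Hspa8, 1700086P04Rik and Acaa1a, brain replicate 3 lay nearer to kidney than the other brain arrays did, as given above.

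For tissue dependence, 1 of 100 splits of the 9 arrays, the real one, gave as many probes (4604, highest other 1710). Since the arrays of a tissue are repeats of 1 pair of pools, the real split could be foreseen to lead. The count shows only that ratios follow the grouping beyond the spread between arrays. It says nothing about chance differences between pools or mice. The highest other kept liver whole, as did the splits with 871, 707 and 692 probes. Any such split except the real one joins brain replicate 3 to a kidney array, so this feature is no support for the structure above. Fitted on 6 arrays, the real splits gave 182 probes between brain and kidney, 1160 between brain and liver and 5782 between kidney and liver, with 0, 0 and 0 for the highest other, and 1 of 10 splits gave as many each time, which is too few splits for a share under 0.05.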

How the results depend on the processing

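Chosen after the data were seen were the tests without multiples of 8, on probes with a single symbol, with medians of lines and columns removed and with an array set; the others were planned. Of 290 alternatives of counts, correlations and list counts, 198 stayed within their limits, 89 moved and 3 reversed, and of 3132 alternatives of 190 named values 3015 kept their side of the threshold, 115 kept only the direction and 2 reversed, both with medians of lines and columns removed (Tfrc in liver to -0.0436 and Abl1 in kidney to 0.0524, neither passing). Equal spread, a filter on missing values and no filter moved nothing by construction and say nothing about stability. Without spot intensities, the limit set by signal over background is unknown.

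With 1 array left out, calls ranged over 2325 to 5091 in brain (2325 without brain replicate 2), 3855 to 7917 in kidney (3855 without kidney replicate 1) and 3273 to 6998 in liver (3273 without liver replicate 3). Tissue dependence ranged over 2531 to 6685, brain against kidney 183 to 3229, brain against liver 1101 to 2386, kidney against liver 2227 to 5718, shared ratio 655 to 961 and calls of the same sign in 3 tissues 664 to 1179. Correlations ranged over 0.56 to 0.69 (brain and kidney), 0.47 to 0.56 (brain and liver) and 0.39 to 0.44 (kidney and liver), and lists called over 0 to 2 in brain (0 without brain replicate 3; limma's camera), 0 to 0 in kidney and 10 to 11 in liver.

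Fewer or stricter tests lowered the counts by construction: brain, kidney and liver gave 2590, 4138 and 3700 with 1 value per gene, 1327, 2079 and 1892 against a fold of 1.2, 1011, 1083 and 1215 with a 2-fold limit. On a tissue's own arrays brain gave 1564, kidney 7577 and liver 6018. Residual SDs were 0.25, 0.23 and 0.32 on the brain arrays and 0.20 to 0.21 on the kidney and liver arrays. The main fit shared 1 spread per probe over the tissues, which was thus on average below that of brain, and its 4660 brain calls rest on this sharing. How far this accounts for the lower brain count was not tested. With a replicate block, brain against kidney gave 587 and the other counts stayed within 1.5 times; residuals of arrays with the same number had correlations of -0.09 to 0.05. With an array set as a term, tissue dependence gave 2442, brain against kidney 352 and kidney against liver 617, and within the set brain replicate 3 against kidney gave 114. With tissue as a random block, the shared ratio passed 2219.

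Without multiples of 8, the shared ratio passed 483 and 658 had the same sign in 3 tissues. Probes with a single symbol gave 2843 in brain, 156 shared and 516 of the same sign. Both limits together gave 2144 in brain, 3272 in kidney, 3191 in liver and 3000 for tissue dependence. They gave 714 for brain against kidney, 2557 for kidney against liver, 0 shared (refitted with limma) and 197 of the same sign. In the fit on all probes, 1815 of these probes had an unadjusted p under 0.05 for the shared ratio. Medians of lines and columns removed gave 123 shared and 554 of the same sign. For these, fewer probes tested lower a count, and otherwise the cause was not tested.

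Removing the mean over tissues reversed the correlations to -0.27, -0.50 and -0.70, as subtracting a mean of 3 pushes them below 0. For brain and kidney the correlation was 0.58 without multiples of 8, 0.53 with a single symbol, 0.35 with both and 0.57 with medians of lines and columns removed; for brain and liver 0.35, 0.25 and 0.43 for the last 3; for kidney and liver 0.36, 0.29, 0.17 and 0.31. Lists called with an estimated correlation were 0 in brain and 0 in liver (camera), by fry 6, 11 and 19, without multiples of 8 0 in brain, and with the medians removed 2 in kidney. The cause was not tested.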

Other observations

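The lists and genes in this part were picked after their values were seen, and the test of neighbouring genes was set before its result was seen.

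In kidney, Cd74, the invariant chain of MHC class II, rose by 1.01 ± 0.34 (SD, n = 3), H2-Eb1 by 0.71 ± 0.57 and H2-Ab1 by 0.63 ± 0.51. Aqp2 and Aqp3, water channels of the collecting duct, rose by 1.12 ± 0.39 and 1.07 ± 0.14. Of 18 genes of the distal tubule and collecting duct 5 rose, 1 fell and 12 did not pass (5 and 1 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.199, and adjusted p = 0.871 with an estimated correlation). With medians of lines and columns of spots removed, camera called this list (adjusted p = 0.00367) and MHC class II (adjusted p = 0.0134).

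In liver, genes of glucose metabolism went both ways: Irs2 rose by 2.54 ± 0.10 (SD, n = 3) and Gys1, a glycogen synthase, by 0.95 ± 0.08, while G6pc had -2.73 ± 0.13 and Pygl, the liver glycogen phosphorylase, -0.96 ± 0.13. Of the 30 genes 3 rose, 9 fell and 18 did not pass (3 and 10 adjusted over the list alone; adjusted p = 0.441, and adjusted p = 0.873 with an estimated correlation). In brain, Mog, a myelin protein, had -0.97 ± 0.48 and Olig1, a factor of oligodendrocytes, -0.68 ± 0.35, and of 15 oligodendrocyte genes 5 fell, 0 rose and 10 did not pass (6 fell adjusted over the list alone; adjusted p = 0.227, and adjusted p = 0.873 with an estimated correlation).

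It was asked whether stretches of the genome in which the strains differ could give neighbouring genes similar strain ratios. Over 11805 pairs of neighbours the Spearman correlation of mean ratios was 0.00461 (p = 0.6, 10000 shuffles), so no such similarity was found.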
